A study of Mus musculus with 11 samples.

How the data were processed

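RNA was measured in follicular (FO) B cells and marginal zone (MZ) B cells flow-sorted from the spleens of mice. The mice carried loxP-flanked Rack1 alleles, either without Cre (control) or with Cre driven from the Cd19 locus (Rack1-deleted). Rack1 encodes a scaffold protein of the small ribosomal subunit. Per the labels' protocols, full-length cDNA was made by oligo(dT) priming and template switching from a small amount of RNA, amplified by PCR, fragmented with an enzyme and sequenced as paired ends. The labels give flow sorting but not the markers used. No step of that protocol is stated to keep the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

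The deposited tables hold whole-number counts per gene, not normalized, with a table for the 5 FO B libraries and another for the 6 MZ B libraries. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with the mouse build GRCm38. The notes do not give the role of each tool or its settings. The tables list 55401 gene IDs, of which 55141 matched a symbol in GENCODE mouse release 21 (GRCm38). The 260 IDs without a name were left out of library sizes and tests and held at most 0.0346% of a library's counts. Counts of 4 were in excess in most libraries. In control FO B library 3, 947, 1603 and 531 genes had 3, 4 and 5 counts, while in control MZ B library 2 there were 640, 611 and 376. The cause is not known, and an analysis of counts divided by 4 was added after this was seen. Library totals ran from 46081634 to 72352813 counts.

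Groups and replicate numbers were taken from the sample titles: control FO B (n = 2, numbered 1 and 3), Rack1-deleted FO B (n = 3), control MZ B (n = 3) and Rack1-deleted MZ B (n = 3). The labels do not say that replicates are separate mice, so p-values measure the spread between these libraries. Nor do they say whether FO B and MZ B libraries of the same number come from the same mouse, and the joint fit treats them as unrelated. Pairs of libraries of the same group differed far beyond counting noise (chi-square per degree of freedom from 45.3 to 391). None was therefore treated as a repeated sequencing of another library. The chi-square covers counting noise only, so it cannot show that the libraries come from separate samples.

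Gene tests used edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr on the groups (minimum count 10, minimum total 15), robust quasi-likelihood fits, and Benjamini-Hochberg adjusted p under 0.05. FO B and MZ B were each fitted in their own table. The difference of the Rack1 effect between cell types and the comparison of control MZ B with control FO B came from a joint fit of all 11 libraries with 4 group means. Cell type and table are the same split there, so a table effect on control MZ B against control FO B cannot be separated. CPM values are TMM-scaled within the fit they are quoted from. Errors of log2 fold changes are standard errors computed as the absolute log2 fold change over the square root of the F statistic.

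Before the data were examined, 42 gene lists (pathways, B cell subsets, markers of other cell types and quality genes) were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. The overlap of calls was tested with a two-sided Fisher's exact test on genes tested in both tables. The 2 tables share no libraries.

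Genes named in the text follow a rule fixed beforehand. It takes Rack1, Cd19, Pax5, Cr2, Fcer2a and Cd1d1. In each Rack1 comparison it takes up to 8 genes per direction with the largest log2 fold change among those with adjusted p under 0.05, a mean log2 CPM of at least 2, an established symbol, and no overlap between groups. For each list with adjusted p under 0.05, or with at least 3 members passing, it takes the 2 members with the lowest p, or up to 4 where passing members go both ways. For the interaction it takes the 5 genes with the lowest p among those that meet the same minimum of expression and rule on symbols, and 8 subset markers for the control comparison. Other genes are said to have been chosen after their values were seen.

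The alternatives were DESeq2 size factors, DESeq2 1.42.0, voom with sample quality weights, no filter, a mean CPM of at least 5, unnamed rows kept, immunoglobulin genes left out, a replicate block, a joint fit, an absolute log2 fold change of at least 1, non-robust fits, and each replicate left out in turn. Alternatives added after seeing the data were counts divided by 4, Rack1-deleted FO B libraries 1 and 2 left out together, and a term for or removal of the MZ B libraries with Y chromosome transcripts.

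The fits were tested on simulated counts drawn from the real genes' means and dispersions with 200 genes changed. For FO B (20699 genes), 7.46% of genes changed 2-fold, 49.3% of genes changed 4-fold and 59.1% of genes changed 8-fold were recovered. For MZ B (17368 genes) the shares were 31.3%, 71.6% and 62.1%, and for the interaction (23416 genes) they were 0%, 28.4% and 36.4%. For control MZ B against control FO B (23416 genes) they were 5.97%, 35.8% and 62.1%. No simulated change was called in the wrong direction. Unchanged genes were called 5 times for FO B, 8 for MZ B, 6 for the interaction and 4 for the control comparison. A simulated list of 20 genes, each raised by the same factor, was found by camera in each of the 4 comparisons. Its genes were drawn independently of each other. The simulation therefore cannot show how camera behaves on real lists whose genes move together. Gene positions are 1-based GRCm38 coordinates from GENCODE release 21.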

Results

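Bulk RNA-seq counts were analysed for 11 libraries of sorted splenic B cells in 4 groups: control FO B (n = 2), Rack1-deleted FO B (n = 3), control MZ B (n = 3) and Rack1-deleted MZ B (n = 3). FO B cells recirculate through follicles, and MZ B cells reside next to the marginal sinus of the spleen. The stated aim was to find the genes affected when Rack1 is lost in B cells. Total counts were 51885492 and 55112284 in the control FO B libraries and 46081634 to 57687027 in the Rack1-deleted FO B libraries. They were 65488002 to 72352813 in control MZ B and 64173592 to 68291630 in Rack1-deleted MZ B. Rack1-deleted FO B libraries 1 and 2 listed 33491 and 32881 genes with a count, against 25615 to 27692 in the other FO B libraries. Transcripts of the Y chromosome gene Ddx3y were at 62.3 CPM in Rack1-deleted FO B library 1, 31.3 CPM in Rack1-deleted MZ B library 1 and 35.7 CPM in control MZ B library 2, and at 0 to 6.53 CPM in the others. Xist, transcribed from the inactive X chromosome, was at 0 to 2.96 CPM in those 3 libraries and 105 to 287 CPM in the others.

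The targeted gene was examined first. Rack1 (ENSMUSG00000020372, chromosome 11, 48800332 to 48806434, plus strand) was at 411 ± 86.5 CPM (SD, n = 2) in control FO B and 242 ± 78.6 CPM (SD, n = 3) in Rack1-deleted FO B. In MZ B it was at 718 ± 172 CPM (SD, n = 3) in controls and 440 ± 133 CPM (SD, n = 3) in Rack1-deleted cells. Every Rack1-deleted library was below every control library of its table, but the margins were small. Rack1-deleted FO B library 1 had 328 CPM against 349 CPM in the lower control, and Rack1-deleted MZ B library 3 had 592 CPM against 618 CPM. The log2 fold changes of -0.76 ± 0.30 (SE, adjusted p = 0.45) in FO B and -0.71 ± 0.25 (SE, adjusted p = 0.293) in MZ B did not pass the edgeR test. The counts cover the whole gene, so transcripts that lack the deleted part are still counted. Exons of Rack1 also overlap those of Trim41 and of small nucleolar RNAs.

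Cd19 (ENSMUSG00000030724, chromosome 7, 126408450 to 126414889, minus strand), the B cell co-receptor whose locus carries the Cre, was lower in every Rack1-deleted library. It was at 1630 ± 219 CPM (SD, n = 2) in control and 735 ± 140 CPM (SD, n = 3) in Rack1-deleted FO B. In MZ B it was at 2020 ± 43.6 CPM (SD, n = 3) and 924 ± 146 CPM (SD, n = 3). The log2 fold changes were -1.15 ± 0.25 (SE, adjusted p = 0.139) in FO B and -1.13 ± 0.15 (SE, adjusted p = 0.0355) in MZ B, so the test was passed in MZ B. The MZ B call was kept in 1 of the 6 fits with a library left out. Cre was present only in the Rack1-deleted groups. An effect of the Cre allele at the Cd19 locus therefore cannot be told apart from an effect of Rack1 loss. This holds for Cd19 itself and for every Rack1 comparison below. Pax5, the transcription factor of B cell identity, had log2 fold changes of 0.09 ± 0.37 (SE, adjusted p = 0.959) in FO B and -0.35 ± 0.20 (SE, adjusted p = 0.524) in MZ B. The complement receptor Cr2 (-0.58 and -0.61), the IgE receptor Fcer2a (-0.60 and -0.50) and the lipid-presenting molecule Cd1d1 (-0.16 and -0.58, log2, FO B and MZ B) did not pass either.

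**Figure D1:**
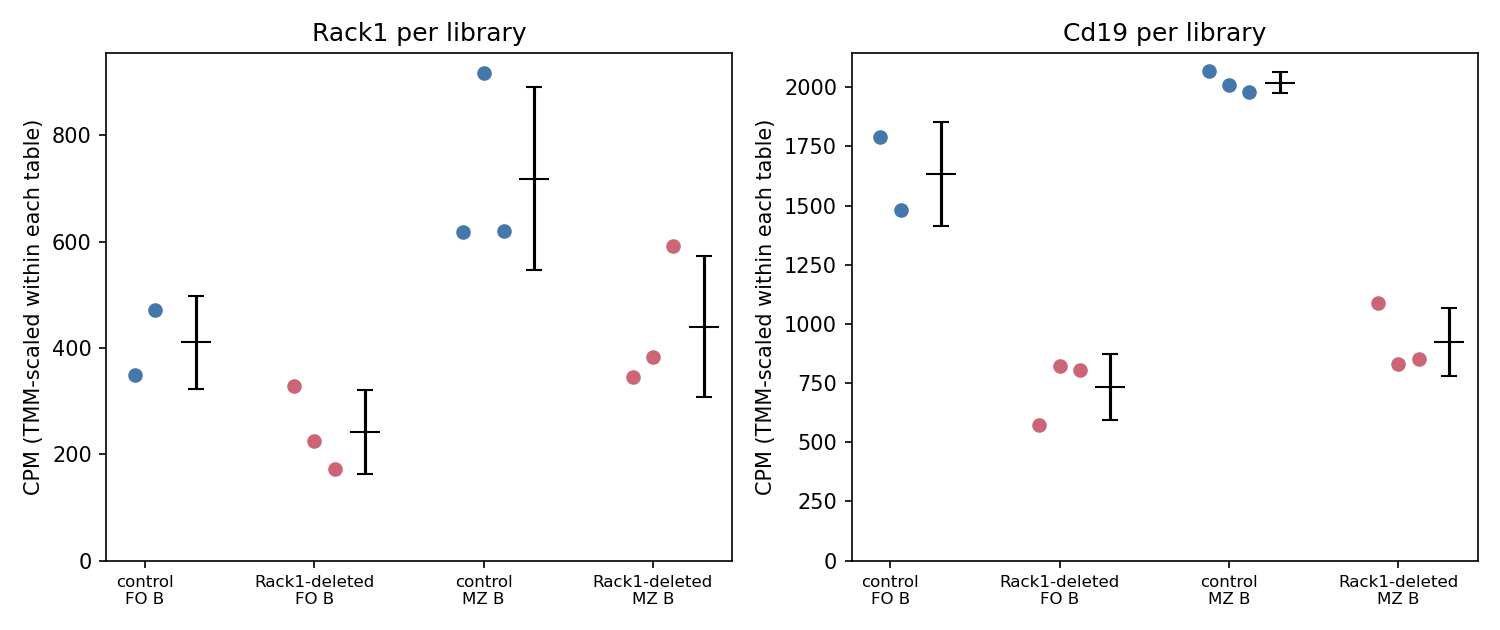
CPM of Rack1 and Cd19 (vertical axes, from 0) in each library of the 4 groups, with dots for libraries and a bar with the mean ± SD beside them. Rack1 in Rack1-deleted FO B spans 173 to 328 CPM against 349 to 472 CPM in controls, and Cd19 in Rack1-deleted MZ B spans 830 to 1090 CPM against 1980 to 2070 CPM.

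The first comparison asked which genes change in FO B cells that carry the Rack1 deletion. Of 20700 genes tested, 15 passed, 13 higher and 2 lower. The largest increase was in Apol11b (chromosome 15, 77633946 to 77643286), of the apolipoprotein L family, at 1.40 ± 0.732 CPM (SD, n = 2) in controls and 111 ± 29.6 CPM (SD, n = 3) in Rack1-deleted cells (log2 fold change 6.31 ± 0.47 SE, adjusted p = 0.00899). Genes of red cell precursors rose with it. Alas2, the first enzyme of haem synthesis in erythroid cells, went from 17.5 ± 2.04 CPM to 314 ± 150 CPM (SD, log2 fold change 4.16). Slc4a1, the red cell anion exchanger, had a log2 fold change of 2.64, the Rh antigen gene Rhd 2.65, Tmcc2 2.75 and Cldn13 2.76. Eps8l1 (4.72) and the Fc gamma receptor gene Fcgr1 of myeloid cells (2.80) also rose. Adjusted p lay between 0.0375 and 0.0493 for these 7 genes. The genes that fell were Jun, an immediate early transcription factor (157 ± 30.3 to 35.8 ± 3.85 CPM, SD, log2 fold change -2.13, adjusted p = 0.0375), and Hspa1b, a heat-inducible chaperone (27.0 ± 28.5 to 0.400 ± 0.0444 CPM, SD, adjusted p = 0.0493). Its near-identical neighbour Hspa1a had 47.7 ± 56.5 CPM in controls and 0.586 ± 0.0275 CPM in Rack1-deleted cells (SD, adjusted p = 0.0654). Reads of these paralogs may have been split between them by the counting. The count of 15 became 0 without control library 1 or without Rack1-deleted library 2, 4 (1 higher, 3 lower) without control library 3, 162 without Rack1-deleted library 1 and 35 without Rack1-deleted library 3. Apol11b was kept in 3 of the 5 fits with a library left out, Hspa1b in 1, and the other 8 named genes that passed in 2. The count was 4 (3 higher, 1 lower) with DESeq2 size factors, 591 with DESeq2 and 62 without Rack1-deleted libraries 1 and 2, the latter an alternative chosen after seeing the data.

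In FO B, 18 of the 42 gene lists passed camera with the preset correlation, 8 upward and 10 downward, and 0 passed with an estimated correlation. The lists of other blood cell types were among the upward ones. All 12 erythroid markers had positive log2 fold changes (median 2.86), 2 passed over all genes (Alas2 and Slc4a1) and 12 passed adjusted over the list alone (camera adjusted p = 6.73e-32, and adjusted p = 0.221 with an estimated correlation). Erythroid markers took 0.179% and 0.301% of counts in the control libraries and 7.07%, 3.87% and 1.26% in the Rack1-deleted libraries. All 20 monocyte and macrophage markers were positive (median 1.51), with 1 passing over all genes, Fcgr1, and 18 adjusted over the list alone (adjusted p = 1.81e-37, and adjusted p = 0.195 with an estimated correlation). Fcgr4 went from 4.91 ± 0.0244 to 30.8 ± 10.1 CPM (SD, adjusted p = 0.0502). Neutrophil markers had a median of 1.21 with 7 of 14 passing adjusted over the list alone (adjusted p = 1.59e-11, and adjusted p = 0.221 with an estimated correlation), and Cxcr2 had a log2 fold change of 1.19 and Ly6g 1.96, neither passing in edgeR. Platelet and megakaryocyte markers had a median of 1.84 with 7 of 11 passing adjusted over the list alone (adjusted p = 2.94e-09, and adjusted p = 0.456 with an estimated correlation), with Pf4 at 3.11 and Gp9 at 2.76. Stromal and endothelial markers (median 1.52, Vwf 1.84 and Stab2 1.52) passed at adjusted p = 0.0122, and at adjusted p = 0.456 with an estimated correlation did not. Dendritic cell markers (median 0.64, Clec10a 2.04 and Batf3 1.5) had adjusted p = 0.0136, and adjusted p = 0.499 with an estimated correlation. The dendritic and the stromal list were each kept in 3 of the 5 fits with a library left out.

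Interferon-stimulated genes and cell cycle genes were the other upward lists in FO B. Of 34 interferon-stimulated genes, 32 were positive (median 0.76), 0 passed over all genes and 13 passed adjusted over the list alone (adjusted p = 1.18e-14, and adjusted p = 0.456 with an estimated correlation). The antiviral gene Rsad2 went from 11.7 ± 2.97 to 153 ± 75.3 CPM (SD, adjusted p = 0.0502), and Ifit3b had a log2 fold change of 1.41. Of 35 cell cycle genes, 32 were positive (median 0.79) and 11 passed adjusted over the list alone (adjusted p = 1.47e-09, and adjusted p = 0.631 with an estimated correlation), with the kinetochore gene Cenpf at 1.68 and the mitotic kinase gene Cdk1 at 1.61. Every Rack1-deleted FO B library also had the higher erythroid share. A link of these lists to that share was not tested library by library.

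Of the 10 downward lists in FO B, 3 were lists of B cell genes, and the others ranged from T cell markers to ribosomal proteins. In B cell receptor signalling, 31 of 34 genes were negative (median -0.30), and 1 passed adjusted over the list alone (adjusted p = 4.38e-07, and adjusted p = 0.631 with an estimated correlation). It includes Cd19, and Malt1, a scaffold of NF-kB activation, went from 178 ± 15.0 to 86.8 ± 24.5 CPM (SD, adjusted p = 0.239). FO B cell genes had a median of -0.38, with 0 of 16 passing (adjusted p = 0.000131, and adjusted p = 0.524 with an estimated correlation), Cxcr4 at -0.74 and Cd55 at -0.62. Pax5-activated genes had a median of -0.26 (adjusted p = 0.00155, and adjusted p = 0.631 with an estimated correlation), while its member Bst1 was at 1.42. Immediate early genes had a median of -0.25 (adjusted p = 8.73e-05, and adjusted p = 0.456 with an estimated correlation), with Jun passing and Fos at -1.22 (adjusted p = 0.141). The heat shock list was called downward (adjusted p = 0.00483, and adjusted p = 0.456 with an estimated correlation) although its median was 0.01 and its mean -0.89, because Hspa1a and Hspa1b lay far below the rest. T cell markers had a median of -0.34 (adjusted p = 0.000101, and adjusted p = 0.631 with an estimated correlation), with Themis at -0.97 and Cd3e at -0.82. Cholesterol synthesis (median -0.21, Srebf2 -0.65, Ldlr -0.76) and Wnt and PKC partners of RACK1 (median -0.21, Map2k7 -0.54, Ptprm 1.37) had adjusted p = 0.0167 and 0.0264, and adjusted p = 0.699 each with an estimated correlation. Small ribosomal subunit proteins (median -0.05, Rps27 -0.66, Rps21 -0.60) and large ribosomal subunit proteins (median -0.03, Rpl7a 0.65, Rplp2 -0.57) were at the edge. They had adjusted p = 0.0406 each, and adjusted p = 0.866 and 0.889 with an estimated correlation. Both ribosomal lists and the Wnt and PKC list were each kept in 2 of the 5 fits with a library left out.

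The second comparison asked the same of MZ B cells. Of 17368 genes tested, 37 passed, 34 higher and 3 lower. Apol11b rose here as well, from 2.08 ± 1.60 to 67.8 ± 3.53 CPM (SD, n = 3 each, log2 fold change 5.03 ± 0.56 SE, adjusted p = 0.0135). The erythroid genes formed the largest group. Alpha globin Hba-a2 went from 339 ± 57.0 to 4930 ± 2150 CPM (SD, log2 fold change 3.86, adjusted p = 0.00561), beta globin Hbb-bt from 421 ± 89.8 to 3500 ± 1500 CPM, Alas2 from 20.7 ± 6.44 to 232 ± 22.1 CPM and glycophorin A gene Gypa from 3.60 ± 0.939 to 30.1 ± 7.79 CPM (SD). Trim10 (log2 fold change 3.51), Snca (3.48) and Tmcc2 (3.36) also rose. Globin genes are near-identical copies, so the split between copies is uncertain. The genes that fell under the naming rule were Cd19, described above, and Erlec1, a lectin of endoplasmic reticulum quality control (chromosome 11, 30930774 to 30954335), from 30.9 ± 1.92 to 9.69 ± 1.05 CPM (SD, log2 fold change -1.67, adjusted p = 0.0128). The count of 37 became 5, 12 and 8 without control library 1, 2 or 3, and 14 without Rack1-deleted library 2. Alas2 was kept in 6 of the 6 fits with a library left out, Snca in 5, Apol11b, Hba-a2 and Gypa in 4, Hbb-bt, Trim10 and Erlec1 in 3, and Tmcc2 in 1. The count was 691 (446 higher, 245 lower) with DESeq2, and 2 without the libraries with Y chromosome transcripts, chosen after seeing the data.

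In MZ B, 17 lists passed camera with the preset correlation, 11 upward and 6 downward, and 0 passed with an estimated correlation. All 12 erythroid markers were positive (median 2.60), 9 passed over all genes, among them the carbonic anhydrase gene Car2 (22.7 ± 2.36 to 116 ± 16 CPM, SD, adjusted p = 0.00248), and 11 adjusted over the list alone (camera adjusted p = 5e-71, and adjusted p = 0.0663 with an estimated correlation). Erythroid markers took 0.272% to 0.363% of counts in controls and 1.68% to 3.53% in Rack1-deleted libraries. All 34 interferon-stimulated genes were positive (median 0.68), 1 passed over all genes and 21 adjusted over the list alone (adjusted p = 6.14e-26, and adjusted p = 0.385 with an estimated correlation). Rsad2 rose from 15.6 ± 1.17 to 106 ± 26.8 CPM (SD, adjusted p = 0.00327), and Ifit1 was at 1.49 (adjusted p = 0.0553). All 35 cell cycle genes were positive (median 0.89, adjusted p = 2.51e-15, and adjusted p = 0.403 with an estimated correlation), 10 passing adjusted over the list alone, with the cyclin genes Ccnb1 at 1.19 and Ccna2 at 1.33.

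Monocyte and macrophage markers were positive in 20 of 20 genes in MZ B (median 1.20, adjusted p = 5.51e-18, and adjusted p = 0.403 with an estimated correlation). Of these, 13 passed adjusted over the list alone and 2 over all genes, Csf1r (35.8 ± 11.6 to 121 ± 19.6 CPM, SD, adjusted p = 0.0492) and Mafb (4.2 ± 0.191 to 12.8 ± 2.17 CPM, SD, adjusted p = 0.0404). Neither call was kept in any of the 6 fits with a library left out (adjusted p up to 0.166 for Csf1r and 0.23 for Mafb). Csf1r is also on the list of Pax5-repressed genes, which had a median of 0.38 (adjusted p = 0.00111, and adjusted p = 0.403 with an estimated correlation) with Fcer1g at 1.18. Neutrophil markers were positive in 14 of 14 genes (median 1.42, 13 passing adjusted over the list alone, adjusted p = 2.51e-15, and adjusted p = 0.371 with an estimated correlation), with Mmp8 at 1.67 and Lcn2 at 1.95. Dendritic cell markers (median 0.51, Itgax 1.48, Flt3 0.65) had adjusted p = 0.00363, and adjusted p = 0.371 with an estimated correlation. Platelet markers (median 1.32, Tubb1 2, Pf4 1.38) had adjusted p = 0.00131, and adjusted p = 0.471 with an estimated correlation. T cell markers (median 0.27, Cd4 1.21, Tcf7 0.96) had adjusted p = 0.0195, and adjusted p = 0.75 with an estimated correlation. With a library left out, the T cell list was kept in 3 of the 6 fits and the stromal list, given below, in 2. B-1 and innate-like B cell genes (median 0.38, Bhlhe40 0.95, Spn 0.75) had adjusted p = 0.00127, and adjusted p = 0.403 with an estimated correlation. Stromal and endothelial markers (median 1.41) had adjusted p = 0.0456, and adjusted p = 0.403 with an estimated correlation, with Pdgfrb at 0.0374 ± 0.0647 CPM in controls and 2.01 ± 1.04 CPM in Rack1-deleted cells (SD) and Stab2 at 1.77.

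Genes of the ribosome and of oxidative phosphorylation were lower as lists in MZ B. Of 33 small ribosomal subunit proteins, 33 were negative (median -0.57), and 17 passed adjusted over the list alone (adjusted p = 5.63e-25, and adjusted p = 0.403 with an estimated correlation). Of 48 large ribosomal subunit proteins, 47 were negative (median -0.57), and 33 passed adjusted over the list alone (adjusted p = 2.53e-29, and adjusted p = 0.403 with an estimated correlation). No member passed over all genes in edgeR, while the 4 members named here passed with DESeq2, with voom and at a mean CPM of at least 5. Of 13 alternative settings, Rps28 passed in 6, Rps27 in 5, and Rpl41 and Rpl35 in 4 each. Each of the 4 passed in 0 of the 6 fits with a library left out. Rps28 went from 47.2 ± 7 to 21.3 ± 2.37 CPM (adjusted p = 0.0541), Rps27 from 446 ± 35.7 to 219 ± 36.6 CPM, Rpl41 from 535 ± 65.3 to 254 ± 66.1 CPM and Rpl35 from 669 ± 88.4 to 308 ± 80.7 CPM (SD). Nuclear-encoded oxidative phosphorylation genes were negative in 71 of 75 (median -0.36, Ndufa2 -0.76, Ndufa7 -0.64, adjusted p = 5.51e-18, and adjusted p = 0.403 with an estimated correlation). Mitochondrially encoded mRNAs were negative in 13 of 13 (median -0.62, mt-Atp6 -0.83, mt-Nd3 -0.93, 10 passing adjusted over the list alone, adjusted p = 3.02e-13, and adjusted p = 0.403 with an estimated correlation). Antigen presentation by MHC class II (median -0.22, Cd74 -0.54, Ifi30 0.57) had adjusted p = 0.0101, and MZ B cell genes (median -0.12, Cd1d1 -0.58, Ebi3 0.82) had adjusted p = 0.0394. Both had adjusted p = 0.403 with an estimated correlation. With a library left out, the MHC class II list was kept in 4 of the 6 fits and the MZ B cell list in 3.

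**Figure D2:**
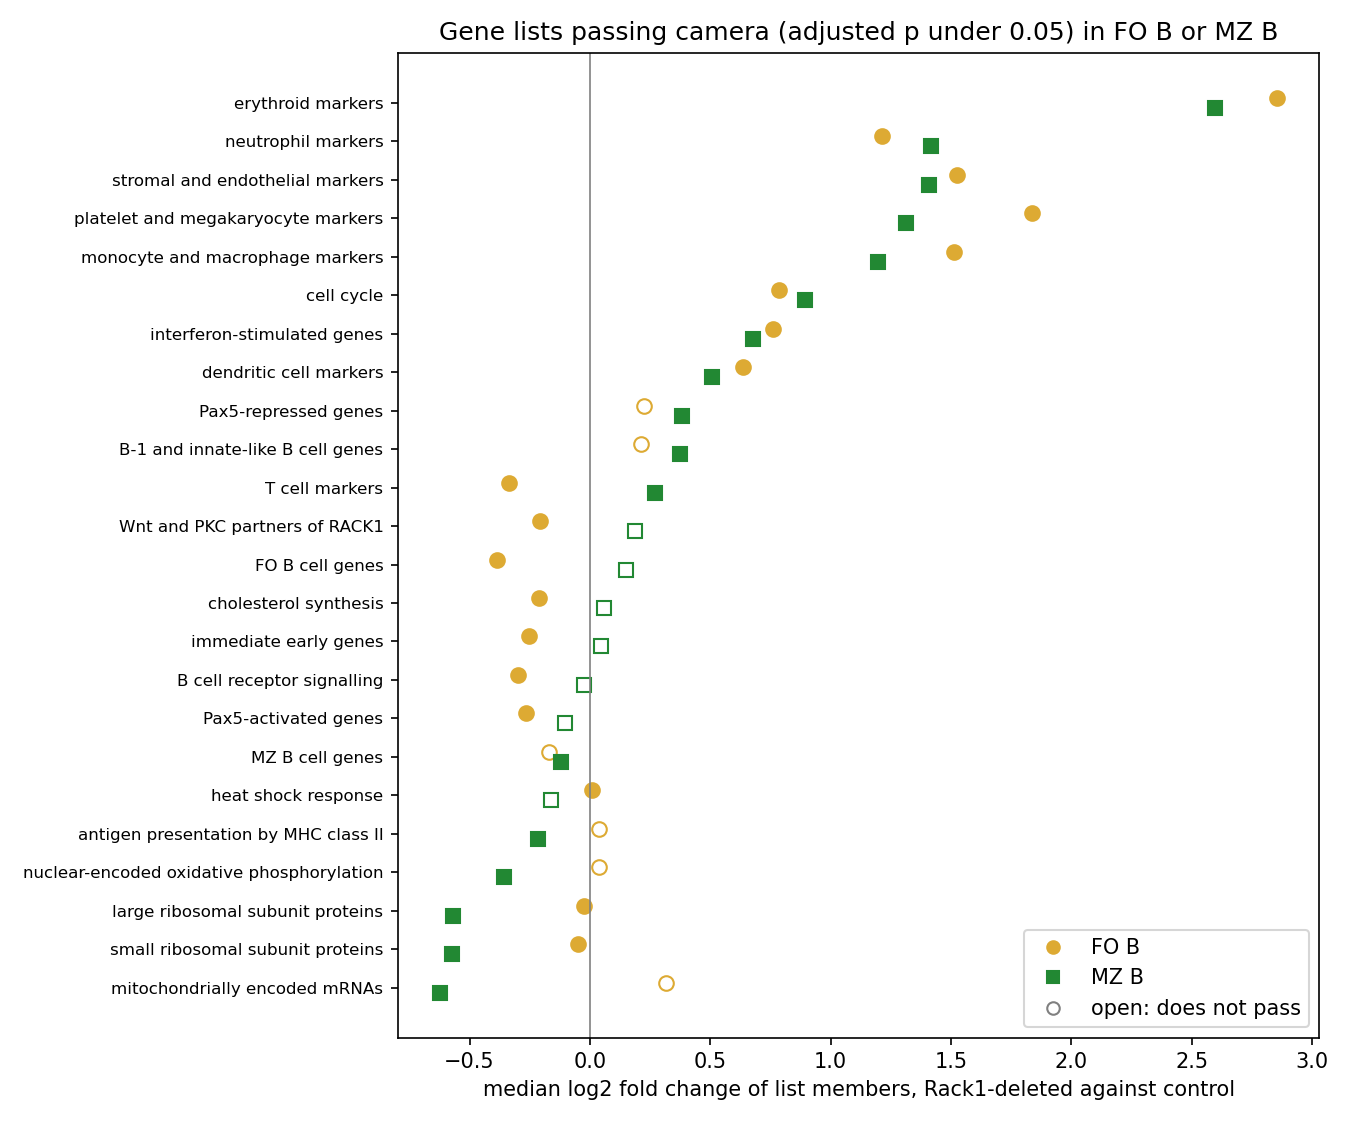
Median log2 fold change (horizontal axis) of the gene lists that passed camera in FO B or MZ B, with circles for FO B and squares for MZ B and open symbols where the list did not pass. The erythroid medians are 2.86 in FO B and 2.60 in MZ B, and the ribosomal medians are near 0 in FO B and -0.57 in MZ B.

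**Figure D3:**
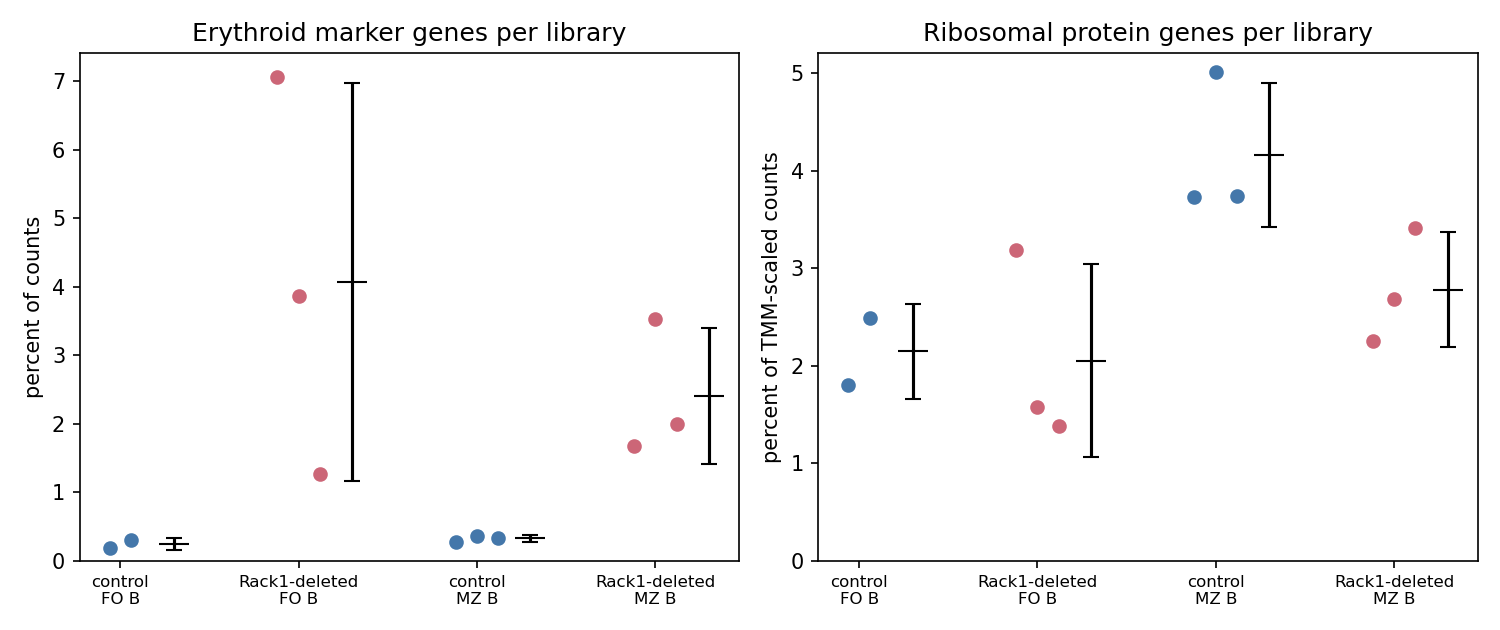
Percent of counts in erythroid marker genes (left) and percent of TMM-scaled counts in ribosomal protein genes (right) in each library, with a bar for the mean ± SD. Erythroid shares are 1.26% to 7.07% in Rack1-deleted FO B against 0.179% to 0.301% in controls, and ribosomal protein shares in MZ B are 2.25% to 3.41% against 3.73% to 5.01%. In FO B, ribosomal protein shares are 3.19%, 1.58% and 1.38% in Rack1-deleted libraries 1, 2 and 3 against 1.8% and 2.49% in controls.

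The calls of the 2 cell types were then compared. Among 16864 genes tested in both tables, 13 were higher in FO B and 34 in MZ B, and 4 genes, Alas2, Apol11b, Slc4a1 and Tmcc2, were in both sets against 0.0262 for independent sets (two-sided Fisher's exact test, p = 9.72e-09). None of the 2 lower genes in FO B and 3 in MZ B was shared. The Fisher test treats genes as independent, but Alas2 and Slc4a1 are both erythroid markers. Members of that list moved together (estimated correlation 0.505 in FO B and 0.477 in MZ B). Whether FO B and MZ B libraries share mice is also not known. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.362 and Spearman rho = 0.24. The overlap was 0 without control FO B library 1 or Rack1-deleted FO B library 2, 23 without Rack1-deleted FO B library 1 and 16 without Rack1-deleted FO B library 3. It was 2 without control FO B library 3, without control MZ B library 1 or 3, or without Rack1-deleted MZ B library 2.

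Whether the Rack1 effect differed between the cell types was tested directly. Of 23416 genes, 0 passed the edgeR interaction test, with 1264 at an unadjusted p under 0.05, while DESeq2 called 19 and voom with quality weights 0. Among genes with an established symbol and a mean log2 CPM of at least 2, the 5 with the lowest p were Mbd2, a reader of methylated DNA (interaction log2 1.85 ± 0.29 SE, adjusted p = 0.341), the ubiquitin ligase gene Znrf2 (2.04 ± 0.32), the RNA-binding gene Qk (1.83), Zfpm1 (2.72) and Ms4a7 (-2.19). None of them passed in edgeR, and all 5 passed with DESeq2 (adjusted p from 7.81e-05 to 0.0209). Mbd2 was at 60.6 ± 10.3 CPM in control and 58.8 ± 2.67 CPM in Rack1-deleted FO B, and at 22.9 ± 2.32 CPM in control and 79.7 ± 20.9 CPM in Rack1-deleted MZ B (SD). Without Rack1-deleted FO B library 2, 1 gene passed.

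The control libraries checked the sort. In control MZ B against control FO B, 4152 of 23416 genes passed, 1602 higher and 2550 lower. Known MZ B markers were higher in MZ B: Cd9 (38.1 ± 1.11 against 225 ± 25.1 CPM, SD, log2 fold change 2.56), Cd1d1 (2.26), the Notch target Dtx1 (2.36), the sphingosine receptor S1pr3 (3.44) and Cr2 (1.02, adjusted p = 0.0471). Known FO B markers were lower: Fcer2a (992 ± 22.3 against 120 ± 49.6 CPM, SD, log2 fold change -3.05), the homing receptor Sell (-1.15) and the transcription factor Klf2 (-2.64). The Cr2 call was kept in 5 of the 11 fits with a library left out (adjusted p up to 0.269), and the other 7 markers passed in all 11. Of 23 MZ B cell genes, 17 passed upward and 1 downward (camera adjusted p = 1.21e-23, and adjusted p = 0.0354 with an estimated correlation). Of 16 FO B cell genes, 12 passed downward and 1 upward (adjusted p = 5.77e-16, and adjusted p = 0.119 with an estimated correlation). Large ribosomal subunit proteins were higher in MZ B, with 32 of 48 passing upward (median 1.12, adjusted p = 2.29e-20, and adjusted p = 0.606 with an estimated correlation). Mitochondrially encoded mRNAs moved with them (12 of 13 passing upward, median 1.25, adjusted p = 2.97e-11), as did nuclear-encoded oxidative phosphorylation genes (30 of 75 passing upward, adjusted p = 5.57e-19), each with adjusted p = 0.606 with an estimated correlation. The count was 996 without control FO B library 1, 2147 without control FO B library 3 and 2450 without control MZ B library 2.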

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

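The tests of length bias and of dilution were chosen after the result was seen. A difference of the Rack1 effect between cell types was found by camera on the interaction (MZ B effect minus FO B effect) for 13 gene lists, each given by its median interaction log2. It was negative for mitochondrially encoded mRNAs (-0.76), large (-0.49) and small (-0.48) ribosomal subunit proteins, nuclear-encoded oxidative phosphorylation (-0.43), monocyte and macrophage markers (-0.43) and antigen presentation by MHC class II (-0.26). It was positive for T cell markers (0.53), FO B cell genes (0.42), immediate early genes (0.36), Wnt and PKC partners of RACK1 (0.36), B cell receptor signalling (0.28; adjusted p = 0.000365), cholesterol synthesis (0.26) and NF-kB pathway and targets (0.21). With an estimated correlation each of the 13 had adjusted p = 0.901, so none passed. No single gene passed the interaction test in edgeR, while DESeq2 called 19. Rack1-deleted FO B library 1 had the highest ribosomal protein share in FO B, 3.19% against 1.58% and 1.38% in its group and 1.8% and 2.49% in controls. Its mitochondrial share was also the highest, 4.7% against 2.31% and 2.01% in its group and 1.64% and 2.89% in controls. How far the negative interaction of these lists rests on this library was not tested.

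Lower ribosomal protein mRNAs in Rack1-deleted MZ B (median log2 fold change -0.57 over 81 genes) were weighed against technical causes. Length bias predicts a like fall in other genes of the same size. The 272 genes matched on coding transcript length and expression had a median of -0.12 ± 0.023 (SE over genes, not libraries). By this median, length could account for only a small part. The test was first run on joined exon length (matched median -0.1) and changed after that result, because 1770 bases at the median is too long for these mRNAs. Dilution by RNA of other cells predicts that B cell genes fall at least as far. Pax5-activated genes lay 0.47 above the ribosomal median, more than the bound of 0.21, which is 2 times the SE of that difference. That SE is taken over genes, which moved together in the small and large ribosomal lists (estimated correlation 0.857 and 0.838). The medians of B cell receptor signalling (-0.02) and MZ B cell genes (-0.12) in MZ B were also above the ribosomal median. For these lists, the values argue against dilution as the whole cause of the fall. The bound does not measure the spread between libraries, so dilution is not ruled out. An effect of Rack1 loss in MZ B cells stays open as a hypothesis, and RNA quality, which was not tested, could also play a part: mitochondrially encoded mRNAs were lower too (13 of 13 negative, median -0.62), and among MZ B libraries control library 2 was highest in both shares (mitochondrial 6.36%, ribosomal protein 5.01%) and Rack1-deleted library 1 lowest (2.96% and 2.25%).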

How the results depend on the processing

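Counts divided by 4, the Rack1-deleted FO B libraries 1 and 2 left out together and both settings on Y transcripts were chosen after seeing the data; the cause of each change was not tested unless stated. FO B genes changed (15) became 4 with DESeq2 size factors, 314 without a filter on low counts, 4 at a mean CPM of at least 5, 591 with DESeq2, 230 with voom and quality weights, 4 with non-robust fits and 62 without Rack1-deleted libraries 1 and 2. MZ B genes changed (37) became 60 without a filter, 171 (125 higher, 46 lower) at a mean CPM of at least 5, 691 with DESeq2, 127 with voom, 79 in the joint fit, 119 with counts divided by 4 and 2 without the libraries with Y transcripts. With a term for Y transcripts the count was again 37, but only 28 of these were calls of the main fit. MZ B lists passing with that term numbered 15 against 17. In the joint fit 18 FO B genes changed, but only 4 of these were among the 15 calls of the main fit. With counts divided by 4, 16 FO B genes changed, and 12 of these were calls of the main fit. Without immunoglobulin genes 17 FO B genes changed, and these held all 15 calls of the main fit. FO B lists (18) became 0 with an estimated correlation and 0 with fry, and MZ B lists (17) became 0 and 1. The interaction count (0) was 19 with DESeq2 and 3 without Rack1-deleted FO B libraries 1 and 2. Control MZ B against control FO B (4152) was 6685 with voom. The overlap (4) was 2 with DESeq2 size factors, 29 without a filter, 2 at a mean CPM of at least 5, 16 in the joint fit, 8 with counts divided by 4 and 12 without Rack1-deleted FO B libraries 1 and 2. Leaving out each replicate gave 0 to 162 FO B genes, 5 to 36 MZ B genes, 18 to 21 FO B lists, 13 to 20 MZ B lists, 0 to 1 interaction genes, 996 to 5254 control genes and 0 to 23 shared calls. Where a lone control FO B library remained, it gave no spread of its own. The overlap was not run under DESeq2 or voom.

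The labels do not pair the replicate numbers. Correlations of same-numbered control and Rack1-deleted libraries were -0.134 and -0.096 in FO B and -0.076 to 0.008 in MZ B, and not every library correlated best with its own number. For same-numbered FO B and MZ B libraries they were 0.049 and 0.009 in controls and -0.024, 0.082 and 0.021 in Rack1-deleted cells. These 5 pairs all matched in whether Ddx3y exceeded Xist, but only 1 pair had Ddx3y above Xist, so whether the 2 cell types came from the same mice is undecided. With the replicate block the counts were 127 FO B genes, 22 MZ B genes and 14 shared calls. With a replicate block by genotype and number, 1 interaction gene and 1501 control genes passed.

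Single genes kept their direction except for 3 that passed in none of these fits. Pax5 in FO B (0.09) was -0.027 with the replicate block, -0.64 without Rack1-deleted libraries 1 and 2, -0.301 without control library 1 and -0.154 without Rack1-deleted library 1, and ran up to 0.544 with a library left out. Cd1d1 in FO B (-0.16) was 0.027 without Rack1-deleted libraries 1 and 2 and -0.334 to 0.013 with a library left out, the latter without Rack1-deleted library 1, and Ldlr in FO B (-0.76) was 0.022 without libraries 1 and 2. Of the other values of single genes, 1658 stayed on their side of the threshold, 133 fell below it and 109 passed it. Depth was not varied.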

Other observations

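The tests of erythroid RNA, of a lower B cell share, of Rack1 deletion as a cause of the erythroid increase, of shared Hspa1 reads, of other heat shock genes and of genes near the Cre locus were chosen after the result was seen. Genes called in MZ B that the naming rule did not take, chosen here after their values were seen, included interferon-inducible genes. Gbp6 rose from 17.4 ± 2.92 to 56.9 ± 10.7 CPM (SD, n = 3 each, log2 fold change 1.71, edgeR adjusted p = 0.0159), Gbp10 had a log2 fold change of 1.88 and Ifi208 rose from 24.2 ± 7.51 to 116 ± 13.4 CPM (SD, log2 fold change 2.26, adjusted p = 0.0131). Its neighbour in the same gene family, Ifi203-ps, fell from 5.77 ± 2.03 to 0.885 ± 0.167 CPM (SD, log2 fold change -2.70, adjusted p = 0.0401). In FO B, Ifi203-ps had a log2 fold change of -3.30 (adjusted p = 0.0696) and Ifi208 one of 1.86 (adjusted p = 0.0964). These genes share sequence, so the split of reads between them is uncertain.

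The genes in this paragraph were likewise chosen after their values were seen, and no list of such enzymes was tested. The enzyme genes Fech and Bpgm of haem and red cell metabolism were called in MZ B. Fech, the last enzyme of haem synthesis, rose from 47.4 ± 6.35 to 118 ± 12.8 CPM (SD), and Bpgm, which makes the red cell effector bisphosphoglycerate, from 45.9 ± 5.28 to 161 ± 48.2 CPM (SD). In FO B, the Rh-associated glycoprotein gene Rhag rose from 2.25 ± 0.606 to 13.9 ± 1.82 CPM (SD, log2 fold change 2.63, adjusted p = 0.0493).

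RNA of erythroid cells carried into the sorted fractions stays open as a cause of the erythroid increase: 100% of the 12 erythroid markers were positive in both cell types, but that restates the increase and favours no cause over another. Hba-a1 went from 1130 ± 598 to 14800 ± 10600 CPM in FO B and from 1570 ± 199 to 7540 ± 3180 CPM in MZ B (SD). Of the 12 markers, 10 in FO B and 8 in MZ B were at 10 CPM or more in controls, and 1 is also on another list, while flow sorting is meant to remove such cells. A lower B cell share that raises every other type alike is argued against. The erythroid median exceeded the T cell median by 3.19 in FO B and 2.33 in MZ B. The bounds of 0.95 and 0.77 were exceeded, but they come from SEs over genes and do not measure the spread between libraries. Only the T cell list was compared in this way. NK and cytotoxic markers had medians of -0.15 in FO B and 0.14 in MZ B. Other lists rose in both, among them monocyte and macrophage (1.51 and 1.20), neutrophil (1.21 and 1.42) and platelet markers (1.84 and 1.32). A lower B cell share that raises other types unequally was not tested. By library, T cell marker shares overlapped between the groups. They were 0.226% and 0.275% in control and 0.173% to 0.264% in Rack1-deleted FO B, and 0.1% to 0.194% and 0.147% to 0.234% in MZ B. Erythroid shares did not overlap in either cell type. An effect of Rack1 deletion within B cells cannot be told apart with 3 libraries a group. Rack1-deleted MZ B library 3, with Rack1 nearest to the controls (592 CPM), had an erythroid share of 2%. MZ B libraries 1 and 2 had shares of 1.68% and 3.53% at 345 and 383 CPM of Rack1. In Rack1-deleted FO B libraries 1, 2 and 3, the shares were 7.07%, 3.87% and 1.26% at 328, 225 and 173 CPM.

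Hspa1a and Hspa1b together were at 74.6 ± 85 CPM in control and 0.986 ± 0.0483 CPM in Rack1-deleted FO B, and at 22.1 ± 29.1 and 0.738 ± 0.146 CPM in MZ B (SD), with control library 1 carrying the control means in both tables (Hspa1a 87.6 against 7.7 CPM in FO B, and 33.9 against 3.26 and 3.03 CPM in MZ B). A shift of reads between the copies is argued against, because the highest Rack1-deleted sum was below the lowest control sum by a log2 ratio of -3.81 in FO B and -2.31 in MZ B, a bound reset after a first look. Handling stress in the controls cannot be told apart: the 13 other heat shock genes had a median of 0.03 in FO B, but at a median of 81.8 CPM in Rack1-deleted cells they could hide a small response, and without control library 1 the Hspa1b log2 fold change of -6.06 was -4.09 (adjusted p = 0.154). A differing region on chromosome 17 stays open too, with 9.19% of the 185 other genes within 2 Mb of Hspa1b at an unadjusted p under 0.05 against 9.42% elsewhere (exact 95% interval 5.44% to 14.3%). By the bounds first set, handling stress and the region would both have been ruled out, and both verdicts were softened after the results, for the baseline and the interval just given.

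As a hypothesis, alleles linked to Cd19 or Rack1 may add calls. Within 20 Mb of these genes, 6 of 47 called genes, Cd19 and Rack1 themselves left out, lay there (Fisher's exact test p = 0.0113), but 3 of the 6 are globin genes of a single cluster. The globin genes were left out only after that result. Without globin genes, 3 of 42 calls lay there, Cdr2, Erlec1 and Igsf6 (Fisher's exact test p = 0.239), which leaves it undecided.

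A second hypothesis was that Rack1 mRNA is lower beyond the change of ribosomal protein mRNAs. In FO B, log2 Rack1 minus the mean log2 of ribosomal protein genes was lower in 3 of 3 Rack1-deleted libraries than in either control, by -0.64 (exact permutation p = 0.1, two-sided, the smallest that 10 arrangements allow). In MZ B the difference was -0.13 (exact permutation p = 0.4, with 0.1 the smallest possible). Rack1-deleted MZ B library 3 (1.25) lay inside the control range of 1.10 to 1.30; by the rule written beforehand this overlap speaks against the hypothesis in MZ B. The verdict was changed to undecided after the result, because a single library makes the overlap.

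The 6 MZ B libraries make 10 splits of 3 against 3, too few for a share under 0.05. For genes, 1 of the 10 splits reached the real count of 37, the real split itself, and the highest other gave 1. For gene lists the real split gave 17 and 2 of the 10 splits, itself included, gave as many or more, with 21 in the highest other, which set control library 1 with Rack1-deleted libraries 2 and 3. Camera with the preset correlation therefore called 9 or more lists in every split of these libraries. Every split but the real one set 2 libraries of a genotype with 1 of the other. Part of any genotype difference thus stays in those splits, and they cannot give the number of calls without such a difference.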
